A study of Macaca fascicularis with 6 samples.

How the data were processed

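RNA sequencing of frozen placenta tissue was available for 6 libraries of the cynomolgus monkey, 2 labelled ICSI, 3 labelled SCNT and 1 labelled TR. Per the file headers, the folder of the TR alignment carries a name that differs from its label, whereas the ICSI and SCNT folders carry theirs, and the library was used as labelled. Per the labels' protocols, total RNA was extracted by phenol and chloroform, polyadenylated RNA was enriched with oligo dT beads, and libraries were sequenced on a DNBSEQ instrument. The molecule label reads genomic DNA, unlike the protocol, and the values were treated as RNA. Fastp 0.23.2, Bowtie2 (no version), SAMtools 1.15.1 and featureCounts 2.0.1 were used, per the submitters' processing notes, which do not give their order or roles. If Bowtie2 aligned the reads to the genome, reads across introns were not split.

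The deposited values were whole fragment counts per gene, which the authors made with featureCounts on the exons of the macFas5 RefSeq annotation, per the file headers. The deposited gene length in bases was the summed length of a gene's exons, per the file headers, and was not used. Per the file headers, reads were paired and counted without strand, so overlapping genes on opposite strands are not told apart. The option for reads with several alignments was not set, so the division of counts among near-identical family members is uncertain. The command named 11 alignments, of which 6 are the libraries analysed and 5 are not analysed here. The table held 28171 lines below its header. The genes MACF1, NEB and TTN were broken over 10 lines by a spreadsheet and were left out, which left 28161 genes, and 26 symbols had been turned into dates. Of 11294 serial LOC identifiers, 5013 had an entry in a RefSeq gene table of assembly T2T-MFA8v1.1 and 721 received a symbol from it. No coordinates were taken from that table. No gene was on chromosome Y or the mitochondrial genome.

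Total counts ran from 14303589 to 18537963 per library, and a count of 3 in the smallest SCNT library equals 0.195 CPM, used as the floor for a group at 0. The floor covers counting error only. Libraries were grouped by label. Genes were kept by edgeR's filterByExpr by group (18226 genes), scaled by TMM (factors 0.883 to 1.0774), and tested in 1 fit of all 6 libraries with edgeR 4.0.16 quasi-likelihood tests in R 4.3.3. The common dispersion was 0.38, with 3 residual degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and all tests were two-sided. The TR library adds no residual degree of freedom and was assumed to vary like the others. CPM values are scaled by TMM, and log2 fold changes are those fitted by edgeR.

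A set of 41 gene lists was fixed before the data were examined, as were the tests, the alternative settings and the rule for naming genes, and 39 lists had at least 5 tested members. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The level of a list in a library is the mean log2 CPM of its members. The median and mean log2 fold changes of a list are taken over the edgeR values of its members. These follow mean counts of a group, where a single high library weighs most, while camera and the levels use log2 CPM. Their signs and sizes can therefore differ. Tissue markers in the lists are not specific to a single cell type, and the macrophage list does not tell fetal from maternal macrophages. Genes named by the rule had a symbol, a mean of at least 1 CPM and complete separation of the groups. The rule took 12 per direction past the threshold, or the 10 of smallest p where fewer than 5 passed. For each list it took members past the threshold over all genes or over the list alone, or otherwise up to 3 members of smallest p, and it also took the 5 genes with most counts in each library.

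The tests were run on simulated data first, in counts drawn from the mean of each gene over all 6 libraries, with 200 genes changed in the SCNT libraries. At the dispersion of the deposited libraries, 1 of 67 genes with a 4-fold change, 28 of 67 with a 16-fold change and 54 of 66 with a 64-fold change were recovered, with 7 false calls among 17721 genes. At a dispersion of 0.05, all 67, 67 and 66 were recovered among 17345 genes. In the simulated list test the shifted list had a camera adjusted p of 3.19e-22 and 0 of 20 unshifted lists were called. Its genes were drawn independently, so it does not test false calls that come from correlation between list members. In the deposited libraries that correlation was estimated at 0.80 for the macrophage list and 0.62 for the decidual list.

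Alternative settings fixed in this way were RLE and upper quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, edgeR's glmTreat, erythroid genes and the 20 genes with most counts left out, chromosome X left out, the ICSI and SCNT libraries alone, the replicate number as a block, and each replicate left out in turn. The position of TR on genes past the threshold could not be computed because none passed, so a setting fixed in the same way, genes with a difference of at least 1 on the log2 scale, was used. Settings chosen after the data were seen were leaving out SCNT replicates 1 and 3 together, a covariate equal to the level of the decidual list, and list tests without the erythroid genes and the 20 genes with most counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.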

Results

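Gene expression was measured by RNA sequencing of polyadenylated RNA in 6 frozen placenta samples of the cynomolgus monkey. The ICSI group (intracytoplasmic sperm injection, fertilisation by injecting a sperm into the oocyte) held 2 samples. The SCNT group (somatic cell nuclear transfer, cloning by moving a body cell's nucleus into an enucleated oocyte) held 3 samples. The TR group held 1 sample. The labels do not spell out the letters TR or say whether that placenta came from a cloned embryo, and the folder of its alignment carries another name than the label. What the comparisons with TR set side by side is therefore known only as far as the label goes. Total counts were 15270002 and 15724171 in ICSI replicates 1 and 2, 18537963, 14303589 and 18296239 in SCNT replicates 1, 2 and 3, and 15672387 in TR. Nothing in the labels says that samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Gestational age and the part of the placenta sampled are not given in the sources used here. The alignment names carry codes whose leading digits are the same in all SCNT libraries and differ in the ICSI and TR libraries. What the codes mark is not stated, and it cannot be told apart from group. The sex of the placentas could not be read, since XIST and the Y-linked genes were not among the genes counted.

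The most abundant transcripts differed between libraries within the SCNT group. IGFBP1, an insulin-like growth factor binding protein abundant in decidualised endometrium, held 20.995% of all counts in SCNT replicate 1 and 20.442% in SCNT replicate 3. It held 6.973% in TR, and it was not among the 5 most counted genes of SCNT replicate 2 or of either ICSI library. In SCNT replicate 2 the leading genes were CSH2 (4.31% of counts) and GHV (3.115%), placental relatives of growth hormone, which also ranked high in ICSI replicate 1 (5.709% and 6.086%). CSH2 and GHV belong to a family of near-identical copies, so the division of counts among its members is uncertain. SERPINE2, a protease inhibitor, led in ICSI replicate 2 with 4.331% of counts. The first principal component of log2 CPM (counts scaled to library size) held 66.84% of the variance of the 2000 most variable genes. SCNT replicate 1 lay at 132.09 and SCNT replicate 3 at 57.49 on it, TR at -10.95, and SCNT replicate 2 at -60.12 beside the ICSI libraries at -49.07 and -69.44.

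The comparison of SCNT with ICSI asked how cloned placentas differ from those of fertilised embryos. Markers of maternal decidual stroma were higher in SCNT, with all 15 measured members positive and a median log2 fold change of 3.79 (camera adjusted p = 3.5e-06; adjusted p = 0.733 with an estimated correlation). The mean log2 CPM of this list was 2.52 ± 1.90 in ICSI (SD, n = 2) and 6.00 ± 2.38 in SCNT (SD, n = 3), and SCNT replicate 2 stood at 3.25 against 7.45 and 7.31 in replicates 1 and 3. WNT4, a signalling ligand used in decidualisation, passed when adjusted over the list alone (log2 fold change 2.38, SE 0.47, edgeR quasi-likelihood adjusted p = 0.0369 over the list). WNT4 measured 2.06 ± 0.66 CPM in ICSI (SD, n = 2) and 10.7 ± 1.71 in SCNT (SD, n = 3). Macrophage and Hofbauer cell markers were also higher, with 20 of 20 members positive and a median of 2.08 (adjusted p = 0.00025; adjusted p = 0.733 with an estimated correlation). The scavenger receptor MARCO measured 77.2, 1.89 and 17.6 CPM in SCNT replicates 1, 2 and 3 against 1.71 and 1.77 in ICSI, and the complement receptor VSIG4 207, 9.12 and 88.1 against 9.20 and 9.39. Endometrial epithelium markers followed with 10 of 13 members positive (adjusted p = 0.0378; adjusted p = 0.733 with an estimated correlation), and this call ended without ICSI replicate 1 or SCNT replicates 1 or 3 (adjusted p up to 0.219). The chemokine CXCL14 in that list measured 243, 18.2 and 97.7 CPM in SCNT replicates 1, 2 and 3 against 8.98 in each ICSI library. The mean log2 fold change of the decidual list went from 3.99 to 6.97 without ICSI replicate 1, since that list stood at 3.86 and 1.17 in ICSI replicates 1 and 2. With SCNT replicates 1 and 3 left out together, a setting chosen after the data were seen that leaves 1 SCNT library assumed to vary like the rest, the mean log2 fold change was -0.09 for the decidual list and -0.80 for the macrophage list (camera adjusted p = 0.537 and 0.00406), and it was -0.90 for the endometrial list. With the decidual level as a covariate, also chosen after the data were seen, the macrophage and endometrial calls ended as well (camera adjusted p = 0.604 and 0.552).

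**Figure D1:**
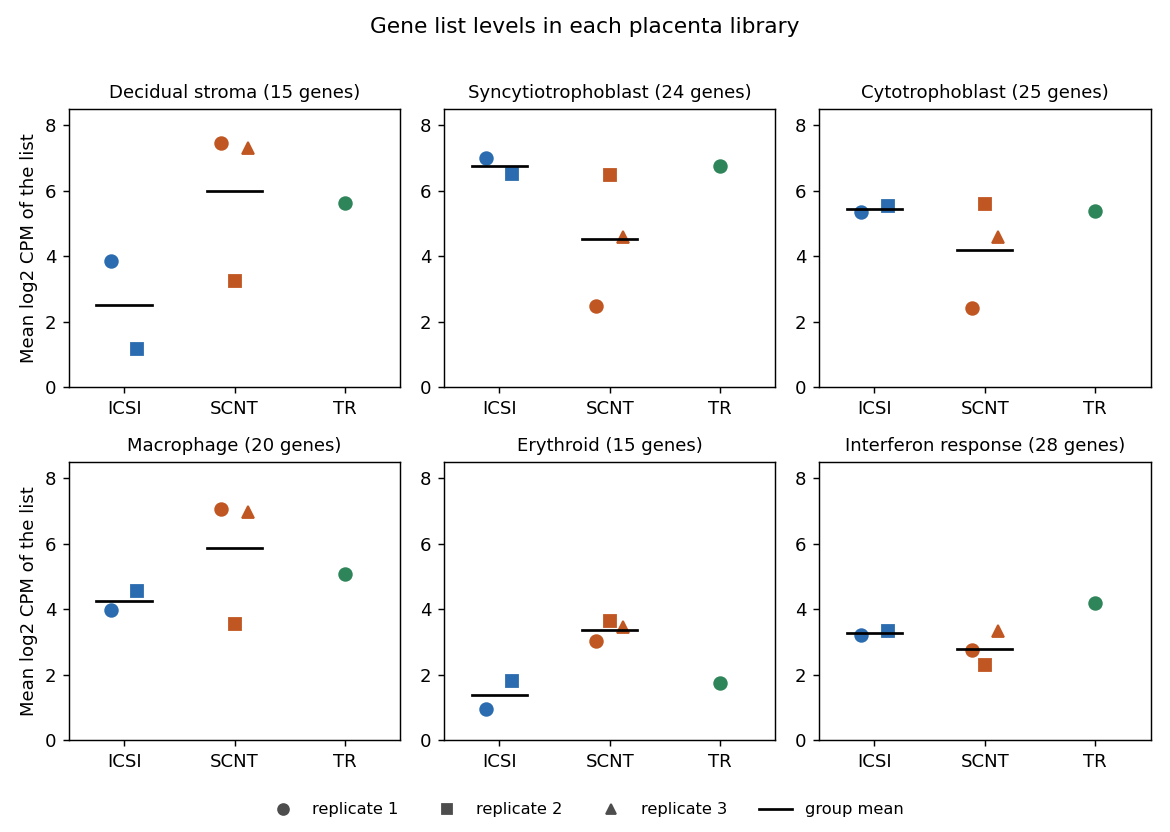
Each panel plots the mean log2 CPM of 1 gene list in the 6 libraries, by group on the horizontal axis, with a marker shape for each replicate and a black line at the mean of groups with more than 1 library. SCNT replicates 1 and 3 sit at 7.45 and 7.31 for the decidual list, SCNT replicate 2 sits beside the ICSI libraries for the decidual, trophoblast and macrophage lists, and the 3 SCNT libraries lie above both ICSI libraries for the erythroid list.

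Trophoblast markers were lower in SCNT. Of 24 measured syncytiotrophoblast genes, the genes of the fused outer layer that makes placental hormones, 16 were negative and 8 positive (median log2 fold change -0.58, camera adjusted p = 0.000342; adjusted p = 0.733 with an estimated correlation). The level of this list was 6.75 ± 0.35 in ICSI (SD, n = 2) and 4.51 ± 2.00 in SCNT (SD, n = 3), with 2.47, 6.47 and 4.59 in SCNT replicates 1, 2 and 3. PAPPA, the pregnancy-associated protease that cleaves IGF binding proteins, passed when adjusted over the list alone (log2 fold change -5.70, SE 0.79, edgeR adjusted p = 0.00951 over the list). Of 25 cytotrophoblast genes 20 were negative (adjusted p = 0.00892; adjusted p = 0.733 with an estimated correlation), a call that ended without SCNT replicate 1 (adjusted p = 0.239). GATA2, a trophoblast transcription factor of that list, measured 437 ± 94.2 CPM in ICSI (SD, n = 2) and 139 ± 122 in SCNT (SD, n = 3), which did not pass with edgeR. Extravillous trophoblast genes went both ways, with a median of -0.49, a mean of 0.01 and a camera adjusted p of 0.199. On the log2 CPM scale the level of this list was 7.55 ± 0.06 in ICSI (SD, n = 2) and 6.83 ± 1.38 in SCNT (SD, n = 3). The deiodinase DIO2 in that list had a log2 fold change of -2.44 (SE 0.51) and the receptor LAIR2 one of 7.31 (SE 2.07). Neither passed with edgeR, while DESeq2 called both (DESeq2 adjusted p = 0.0118 and 0.00046). The mean log2 fold change of the syncytiotrophoblast list was -1.07, and it went to -0.53 without ICSI replicate 1 and to -2.74 without SCNT replicate 2. That of the cytotrophoblast list went from -0.61 to -1.35 without SCNT replicate 2 and to -0.27 without SCNT replicate 1. With SCNT replicates 1 and 3 left out together, the mean log2 fold change was -0.42 for the syncytiotrophoblast list and 0.07 for the cytotrophoblast list, and both calls ended (camera adjusted p = 0.854 and 0.537). Both also ended with the decidual covariate, at -0.70 and 0.12 (camera adjusted p = 0.604 and 0.74).

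Genes of red cell formation were higher in SCNT, and here the 3 SCNT libraries stood together. Of 15 measured erythroid genes 14 were positive, and 9 had every SCNT library above both ICSI libraries (median log2 fold change 2.32, camera adjusted p = 1.33e-06; adjusted p = 0.733 with an estimated correlation). The level of the list was 1.38 ± 0.62 in ICSI (SD, n = 2) and 3.38 ± 0.31 in SCNT (SD, n = 3). The erythroid transcription factor KLF1 measured 0.28 ± 0.19 CPM in ICSI and 2.31 ± 0.52 in SCNT, and ALAS2, the first enzyme of erythroid haem synthesis, 12.4 ± 9.18 and 61.8 ± 20.2 (SD, n = 2 and n = 3). The red cell surface protein GYPA measured 1.38 ± 0.80 and 5.82 ± 1.49 CPM (SD, n = 2 and n = 3). None of the 3 passed with edgeR over all genes or over the list alone (adjusted p = 0.0617 over the list for each). With SCNT replicates 1 and 3 left out together the mean log2 fold change of the list was 2.45 (camera in limma, adjusted p = 2.96e-06).

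Extracellular matrix genes were higher in SCNT, with 28 of 33 members positive (median log2 fold change 1.26, camera adjusted p = 0.000372; adjusted p = 0.733 with an estimated correlation). LOXL2, a collagen cross-linking enzyme, and the collagen chains COL5A1 and COL6A3 passed when adjusted over the list alone (edgeR adjusted p = 0.0484 for each), with log2 fold changes of 2.40 (SE 0.51), 2.80 (SE 0.60) and 2.00 (SE 0.45). Matrix genes stood at 7.53, 7.29 and 8.14 in SCNT replicates 1, 2 and 3 against 6.91 and 6.75 in ICSI, on the scale where the decidual list stood at 7.45, 3.25 and 7.31. Their mean log2 fold change went from 1.13 to 0.39 with the decidual level as a covariate, where the call ended (camera adjusted p = 0.0656), and to 0.42 with SCNT replicates 1 and 3 left out together (camera adjusted p = 0.0114). Immediate early and heat shock genes, which also respond to tissue handling, were positive in 23 of 25 members (adjusted p = 0.000342; adjusted p = 0.733 with an estimated correlation). The transcription factor JUN measured 737, 121 and 833 CPM in SCNT replicates 1, 2 and 3 against 64.8 and 88.7 in ICSI. For this list the mean log2 fold change went from 1.38 to 0.70 without SCNT replicate 3 (camera adjusted p = 0.027) and to 0.41 without SCNT replicates 1 and 3 (camera adjusted p = 0.0479). The decidual covariate brought it to 0.51 and ended the call (camera adjusted p = 0.0589). Inflammatory NF-kB genes were positive in 18 of 24 members (adjusted p = 0.0326; adjusted p = 0.733 with an estimated correlation), and this call ended without ICSI replicate 1 or SCNT replicates 1 or 3 (adjusted p up to 0.202). Inflammatory genes had a mean log2 fold change of 1.45, which went to 2.20 without ICSI replicate 2, to 0.89 without SCNT replicate 3, to -1.15 without SCNT replicates 1 and 3 and to -0.64 with the covariate. The cytokine IL1A measured 28.4, 5.21 and 35.5 CPM in SCNT replicates 1, 2 and 3 against 0.37 and 0.06 in ICSI. Interferon-stimulated genes were lower in SCNT, with 23 of 28 members negative (median -0.46, adjusted p = 0.00569; adjusted p = 0.733 with an estimated correlation), a call that ended without ICSI replicate 2 or SCNT replicate 2 (adjusted p up to 0.185). The interferon list stood at 2.77, 2.29 and 3.33 in SCNT replicates 1, 2 and 3 against 3.21 and 3.34 in ICSI, and lymphoid markers at 4.05, 0.74 and 3.50 against 3.18 and 2.72. Interferon genes had a mean log2 fold change of -0.34, which went to -0.17 without ICSI replicate 2, to -0.20 without SCNT replicate 2 and to -0.63 without SCNT replicate 3. It was -1.13 without SCNT replicates 1 and 3 and -0.999 with the covariate (camera adjusted p = 3e-06 and 0.000124). IRF9, a subunit of the interferon-activated transcription complex, measured 52.9 ± 3.61 CPM in ICSI (SD, n = 2) and 30.4 ± 4.06 in SCNT (SD, n = 3). Smaller shifts passed in limma's camera test for cell cycle genes (29 of 32 positive, median 0.36, adjusted p = 0.0326), cytosolic ribosomal proteins (39 of 44 positive, median 0.32, adjusted p = 0.015) and glycolytic enzymes (14 of 17 positive, median 0.43, adjusted p = 0.0378). Each of the 3 had a camera adjusted p = 0.733 with an estimated correlation. The cell cycle call ended without ICSI replicate 1 or SCNT replicate 2 (adjusted p up to 0.738) and its mean log2 fold change went from 0.36 to 0.57 without ICSI replicate 2, to 0.21 without ICSI replicate 1 and to 0.0595 without SCNT replicate 2, the ribosomal call without ICSI replicate 2 or SCNT replicate 1 (up to 0.151), and the glycolytic call without ICSI replicate 2 or SCNT replicates 2 or 3 (up to 0.286). The ribosomal and glycolytic calls also ended with the covariate (camera adjusted p = 0.779 and 0.604), where the cell cycle list had a mean of 0.91 and kept its call.

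Imprinted genes, expressed from 1 parental copy, were examined because nuclear transfer can alter imprinting. Counts per gene do not tell the parental copies apart, so the levels below do not show whether imprinting was changed. Genes expressed from the maternal copy were lower, with 14 of 22 members negative (median log2 fold change -0.42, camera adjusted p = 0.0378; adjusted p = 0.733 with an estimated correlation), and this call ended without ICSI replicate 1 or SCNT replicates 1 or 3 (adjusted p up to 0.304). The level of this list was 3.15, 5.16 and 4.49 in SCNT replicates 1, 2 and 3 against 5.47 and 5.08 in ICSI, lowest in the libraries where the decidual list was highest. Its mean log2 fold change went from -0.54 to -0.20 with SCNT replicates 1 and 3 left out together (camera adjusted p = 0.814) and to -0.31 with the decidual level as a covariate, also chosen after the data were seen (camera adjusted p = 0.77). The acetyltransferase NAA60 measured 203 ± 63.0 CPM in ICSI (SD, n = 2) and 57.0 ± 12.1 in SCNT (SD, n = 3), and the potassium channel KCNQ1 had a log2 fold change of 0.95 (SE 0.42). Genes imprinted in mice through maternal H3K27me3 were negative in 7 of 8 members (adjusted p = 0.0326; adjusted p = 0.733 with an estimated correlation), a call that ended without ICSI replicate 2 or SCNT replicates 1 or 3 (adjusted p up to 0.286). This list stood at 2.23, 3.96 and 2.65 in SCNT replicates 1, 2 and 3 against 4.27 and 4.63 in ICSI, and its call also ended with SCNT replicates 1 and 3 left out together (camera adjusted p = 0.537) and with the decidual covariate (camera adjusted p = 0.77). The mean log2 fold change of the maternal list went to -0.27 without ICSI replicate 1, to -0.29 without SCNT replicate 1 and to -1.11 without SCNT replicate 2. For the H3K27me3 list it went from -1.39 to -0.49 without ICSI replicate 2 and to -2.39 without SCNT replicate 2. Genes expressed from the paternal copy did not pass limma's camera test (11 of 19 negative, adjusted p = 0.256), nor did genes with imprinting described mainly in primate placenta (11 of 19 negative, adjusted p = 0.271). In the last list RASGRF1, an exchange factor for Ras, measured 10.8 and 4.96 CPM in ICSI and 0.11, 0.85 and 0.51 in SCNT replicates 1, 2 and 3. The paternal list stood at 2.48 in SCNT replicate 1, and at 5.05 and 4.67 in SCNT replicates 2 and 3 against 4.66 and 5.10 in ICSI. Nutrient transporters were lower (19 of 33 negative, median -0.24, adjusted p = 0.044; adjusted p = 0.733 with an estimated correlation), a call that held without SCNT replicate 3 and ended without each other library (adjusted p up to 0.234). Their mean log2 fold change of -0.52 ran from -0.27 without ICSI replicate 2 to -0.85 without SCNT replicate 2. It was -0.49 with the covariate, where the call ended (camera adjusted p = 0.77), and -0.52 without SCNT replicates 1 and 3. The size of the shift thus stayed about the same in these 2 settings. FABP3, a fatty acid binding protein of that list, passed when adjusted over the list alone (log2 fold change -6.02, SE 0.66, edgeR adjusted p = 0.00387 over the list). In all, 16 of 39 lists passed, 10 higher and 6 lower, and none passed with an estimated correlation or with fry. The other 23 had adjusted p from 0.0865 to 0.853, and in 7 of them the median, the mean and the test differed in sign. Among these, PDGFB of the angiogenesis list, a growth factor that recruits pericytes, passed over the list alone (log2 fold change -2.90, SE 0.46, edgeR adjusted p = 0.021 over the list).

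No single gene of 18226 tested passed for SCNT against ICSI with edgeR's quasi-likelihood test (smallest adjusted p = 0.243). At an unadjusted p under 0.05 there were 1195 genes, 611 higher and 584 lower, against 911 expected by chance, and limma-voom also called 0 genes. DESeq2 called 333, of which 186 were higher and 147 lower. Without SCNT replicate 2 the edgeR count was 268, of which 168 were higher and 100 lower, and 105 genes were shared with the DESeq2 calls. Complete separation of the 5 libraries was seen in 24.1% of genes, where chance gives 20%. The 10 named genes of smallest p that separated the groups were all lower in SCNT, and all 3 SCNT libraries shared the low level. PAPPA (chromosome 15, 21070792 to 21316713 on macFas5) measured 1343 ± 76.1 CPM in ICSI (SD, n = 2) and 25.8 ± 16.7 in SCNT (SD, n = 3), a 52.1-fold difference. FABP3 (chromosome 1, 196661011 to 196668522) measured 102 and 88.4 CPM in the ICSI libraries and 1.46 ± 1.07 in SCNT (SD, n = 3), a 64.9-fold difference. TMEM229B (chromosome 7, 131991562 to 132036650), a membrane protein, had a log2 fold change of -5.08 (SE 0.41) and ZNF711 (chromosome X, 82386170 to 82415217), a zinc finger protein, one of -5.38 (SE 0.46), both with edgeR adjusted p = 0.243. PVRL1 (chromosome 14, 115722309 to 115790752), the adhesion molecule nectin, had a log2 fold change of -3.68 (SE 0.37) and the secretory granule protein SCG3 (chromosome 7, 28671493 to 28707984) one of -5.38 (SE 0.70). The remaining members were TMEFF2 (log2 fold change -6.21), the adhesion molecule KIRREL3 (-3.43), the keratin KRT80 (-3.16) and the AMP deaminase AMPD3 (-2.45). Their edgeR adjusted p ranged from 0.527 to 0.591, and that of PAPPA was 0.698 over all genes. DESeq2 called all 10, and 9 passed edgeR without SCNT replicate 2. The 10 were chosen by small p and separation in these same libraries, so such calls are not independent support.

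**Figure D2:**
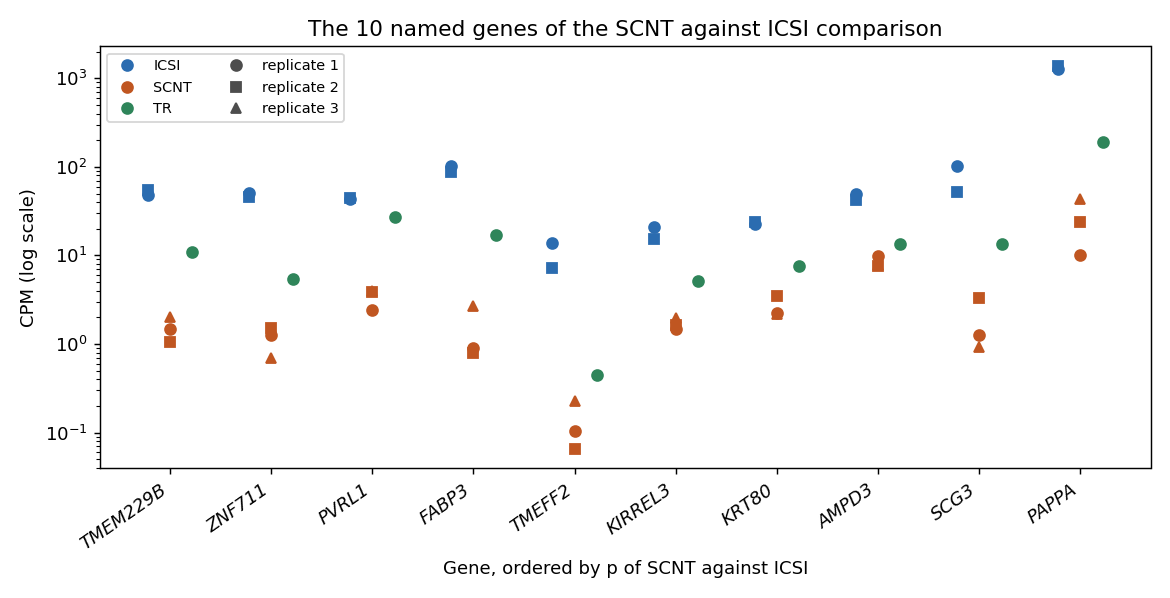
CPM on a log axis of the 10 named genes of the SCNT against ICSI comparison in each of the 6 libraries, with colour for group and marker shape for replicate. The rule that chose the genes required complete separation, and in all 10 the 3 SCNT libraries lie below both ICSI libraries. The TR library lies between the groups in each, as for PAPPA with 193 CPM in TR against 10.1 to 43.3 in SCNT and 1289 to 1397 in ICSI. Genes picked for so wide a gap tend to leave another library in between, so this does not place TR for genes in general.

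The comparison of TR with ICSI set the 1 TR library against 2 ICSI libraries, with TR assumed to vary like the other groups. Decidual stroma markers were higher in TR, with 15 of 15 members positive (median log2 fold change 2.21, camera adjusted p = 2.22e-05; adjusted p = 0.782 with an estimated correlation). The mean log2 fold change of this list went from 2.29 to 5.28 without ICSI replicate 1, as the list stood at 3.86 and 1.17 in ICSI replicates 1 and 2. IGFBP1 measured 69784 CPM in TR against 12592 and 16.9 in the ICSI libraries, and the transcription factor HAND2 had a log2 fold change of 2.21 (SE 1.28). Interferon-stimulated genes were higher, with 25 of 28 members positive and a median of 0.65 (adjusted p = 2.22e-05; adjusted p = 0.782 with an estimated correlation). With the decidual covariate their mean log2 fold change went from 0.85 to 0.42 (camera adjusted p = 0.0495). The antiviral GTPase MX1 measured 54.1 CPM in TR against 19.1 and 11.5, and the ubiquitin-like modifier ISG15 11.5 against 2.52 and 0.71. Steroid hormone synthesis genes were positive in 11 of 14 members (adjusted p = 0.0167; adjusted p = 0.782 with an estimated correlation), a call that ended without ICSI replicate 2 (adjusted p = 0.0998). CYP17A1, the enzyme leading from progestins to androgens, measured 14.9 CPM in TR against 0.59 and 1.06, and FDXR, which feeds electrons to mitochondrial steroid enzymes, 51.0 against 23.4 and 13.8. In limma's camera test immediate early genes (20 of 25 positive, adjusted p = 0.0423) and ribosomal proteins (37 of 44 positive, adjusted p = 0.0426) were also higher, and the H3K27me3-imprinted genes were lower (7 of 8 negative, adjusted p = 0.0423). The 3 lists had a camera adjusted p = 0.782 with an estimated correlation. The immediate early call ended without ICSI replicate 1 (adjusted p = 0.116), the ribosomal call without ICSI replicate 2 or SCNT replicates 1 or 2 (up to 0.292), and the imprinted call without either ICSI library (up to 0.351). The mean log2 fold change of the ribosomal list went from 0.24 to 0.37 without ICSI replicate 1, and that of the H3K27me3 list from -1.06 to -0.53 without ICSI replicate 2. With the decidual covariate the immediate early list went from 0.69 to 0.0945, the H3K27me3 list to -0.0871 and the ribosomal list to -0.0473, and the 3 calls ended (camera adjusted p = 0.673, 0.976 and 0.683). Syncytiotrophoblast genes did not pass, with 12 positive, 12 negative and an adjusted p of 0.986, and the level of the list was 6.76 in TR and 6.75 ± 0.35 in ICSI (SD, n = 2). In all, 6 of 39 lists passed, 5 higher and 1 lower, and the other 33 had adjusted p from 0.0634 to 0.986, with differing signs of median, mean and test in 5.

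No gene passed for TR against ICSI with edgeR (smallest adjusted p = 1) or with limma-voom, and edgeR gave 162 genes at an unadjusted p under 0.05 against 911 expected by chance. A count below chance does not show that TR was like ICSI. The spread in this test was estimated from the ICSI and SCNT libraries alone, and the SCNT libraries differed widely among themselves. TR lay outside the ICSI libraries in 68.19% of genes, where chance gives 66.67%. DESeq2 called 1 gene, PM20D1 (chromosome 1, 64338286 to 64360659), an N-acyl amino acid enzyme at 0.06 CPM in TR and 12.5 and 15.7 in ICSI. LOXL2 had the opposite direction, with 47.4 CPM in TR against 9.72 and 7.38 (log2 fold change 2.47, SE 0.60), with 24.4 to 59.0 CPM in the SCNT libraries. NRXN3, a synaptic adhesion gene, measured 14.9 CPM in TR against 0.15 and 0.12. ZNF711, TMEM229B, TMEFF2 and AMPD3 were among the 10 named genes here too, with log2 fold changes of -3.15 (SE 0.65), -2.23 (SE 0.56), -4.53 (SE 1.07) and -1.76 (SE 0.46). The adaptor APBA1 (-2.88), the neutrophil chemokine receptor CXCR2 (-1.76) and the serotonin receptor HTR5A (-3.52) completed the named genes, none of which passed with edgeR.

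The comparison of TR with SCNT set the 1 TR library against the 3 SCNT libraries. Interferon-stimulated genes gave the smallest p of any list, with 27 of 28 members positive and a median log2 fold change of 1.26 (camera adjusted p = 6.66e-13; adjusted p = 0.496 with an estimated correlation). MX1 measured 54.1 CPM in TR against 4.17 to 13.8 in the SCNT libraries, IFIT3 26.8 against 8.80 to 11.9, and IRF9 66.9 against 26.3 to 34.4. Antigen presentation genes were positive in 10 of 11 members (median 0.96, adjusted p = 0.00187; adjusted p = 0.496 with an estimated correlation), with the peptide transporter subunits TAP1 and TAP2 at 113 and 138 CPM in TR. Syncytiotrophoblast genes were higher, with 17 of 24 members positive (median 1.00, adjusted p = 5.13e-06; adjusted p = 0.985 with an estimated correlation). PAPPA measured 193 CPM in TR against 10.1 to 43.3 in SCNT, and the placental lactogen CSH4, 1 of the near-identical family copies, 2372 against 2.32 to 104. Cytotrophoblast genes passed as well (14 of 25 positive, adjusted p = 0.00854; adjusted p = 0.985 with an estimated correlation), a call that ended without SCNT replicate 1 (adjusted p = 0.67). Steroid hormone synthesis genes were positive in 12 of 14 members (adjusted p = 0.000195; adjusted p = 0.985 with an estimated correlation), with FDXR at 51.0 CPM in TR against 4.90 to 12.8. Without SCNT replicate 2 the mean log2 fold change went from 0.96 to 2.66 for the syncytiotrophoblast list, from 0.48 to 1.27 for the cytotrophoblast list and from 1.22 to 2.40 for the steroid list. It fell to 0.68, 0.15 and 0.965 for these lists without SCNT replicate 1. The steroid list stood at 1.76, 4.17 and 3.03 in SCNT replicates 1, 2 and 3 and at 4.81 in TR. With SCNT replicates 1 and 3 left out together, the mean log2 fold change was 1.99 for the interferon list, 1.95 for antigen presentation, 0.29 for the syncytiotrophoblast list, -0.19 for the cytotrophoblast list and 0.67 for steroid synthesis. In that setting the steroid, syncytiotrophoblast and cytotrophoblast calls ended (camera adjusted p = 0.191, 0.928 and 0.285).

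Erythroid genes were lower in TR than in SCNT, with 14 of 15 members negative (median log2 fold change -2.24, camera adjusted p = 8.41e-08; adjusted p = 0.496 with an estimated correlation). GYPA measured 0.70 CPM in TR against 4.32 to 7.30 in SCNT, and the red cell anion exchanger SLC4A1 0.83 against 4.92 to 12.2. The level of the list was 1.75 in TR, within the 0.94 and 1.82 of the ICSI libraries. Cell cycle genes (28 of 32 negative, adjusted p = 0.00778) and extracellular matrix genes (28 of 33 negative, adjusted p = 0.0186) were also lower, each with adjusted p = 0.985 with an estimated correlation. The cell cycle call ended without SCNT replicate 2 (adjusted p = 0.508) and the matrix call without SCNT replicate 3 (adjusted p = 0.292). The mean log2 fold change of the matrix list turned from -0.67 to 0.0489 with SCNT replicates 1 and 3 left out together (camera adjusted p = 0.577), and the call ended with the decidual covariate at -0.41 (camera adjusted p = 0.0503). In all, 8 of 39 lists passed, 5 higher and 3 lower, and the other 31 had adjusted p from 0.0524 to 0.986, with differing signs of median, mean and test in 10.

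No gene passed for TR against SCNT with edgeR (smallest adjusted p = 1) or with limma-voom, and edgeR gave 315 genes at an unadjusted p under 0.05 against 911 expected by chance. Here too the spread came from the ICSI and SCNT libraries alone, so a count below chance does not show that TR was like SCNT. TR lay outside the SCNT libraries in 36.31% of genes, where chance gives 50%. DESeq2 called 23 genes, of which 19 were higher in TR. The 10 named genes of smallest p were all higher in TR. PVRL1 measured 27.5 CPM in TR and 2.43 to 4.00 in SCNT (log2 fold change 2.99, SE 0.41), and TMEM229B 10.9 and 1.04 to 2.00 (2.85, SE 0.44). Keratins of stratified epithelium were among them, with KRT6A (chromosome 11, 51335116 to 51340499) at 66.0 CPM in TR against 1.42 to 4.10. KRT14 (chromosome 16, 53240672 to 53245254) measured 72.3 CPM in TR and 0, 0 and 0.06 in SCNT replicates 1, 2 and 3, with 0.82 and 25.4 in the ICSI libraries. FTHL17, a ferritin-like gene on chromosome X (29296424 to 29297243), had 0 counts in each SCNT library and 5.36 CPM in TR, at least 27.4-fold higher when 3 counts per library are taken as the floor. UBD, a ubiquitin-like modifier induced by inflammatory cytokines, measured 63.0 CPM in TR against 2.80 to 8.52, and the thymic regulator AIRE 52.5 against 0.37 to 2.28. The remaining members were the proton channel OTOP2 (log2 fold change 6.60), the LIM protein CRIP1 (2.61) and MORN3 (4.90).

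Because no gene passed for SCNT against ICSI, the position of TR on passing genes has no value, and it was read on the 4634 genes whose mean log2 CPM differed by at least 1 between the groups. TR lay nearer the ICSI mean in 53.37% of them (95% exact binomial interval 51.92% to 54.81%). This interval treats the genes as independent and leaves out the spread between libraries. In counts simulated from these libraries the share averaged 66.7% with TR drawn at the ICSI mean, 47.85% midway and 29% at the SCNT mean, and 44.82% with no difference between the groups, which lies close to the midway value. Genes lower in SCNT lay nearer ICSI in 64.06% of 2421 cases and genes higher in SCNT in 41.66% of 2213. The share was 66.25% without SCNT replicate 2 and 41.84% without ICSI replicate 1. The simulation also drew genes independently, so its reference values leave out shifts of a library shared by many genes.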

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

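The alternatives that left out SCNT replicates 1 and 3 together, that added the decidual level as a covariate, or that ran the list tests without the erythroid genes and the 20 genes with most counts were chosen after seeing the data, and the others before. No gene passed in any of the 3 comparisons with RLE or upper quartile scaling, either filter, limma-voom, glmTreat, top genes or chromosome X left out, or the decidual covariate. DESeq2 called 333 genes for SCNT against ICSI, 1 for TR against ICSI and 23 for TR against SCNT, and gave no adjusted p for 354 genes. Leaving out each library in turn gave 0 to 268 genes for SCNT against ICSI, the 268 without SCNT replicate 2, and 0 in the TR comparisons. Scaling moved the median log2 fold change of all genes for TR against SCNT from -0.12 (TMM) to -0.15 (RLE) and -0.20 (upper quartile), and for SCNT against ICSI from 0.06 to 0.07 and 0.14. With the replicate block, which pairs libraries sharing a number, 0 genes and 10 lists passed for SCNT against ICSI. Only 2 numbers are shared, and libraries with the same number had r of 0.07 and 0.20 after group means were removed. Libraries with different numbers had r from -0.255 to 0.255, so the shared numbers did not stand out. Nothing in the labels says that the numbers pair animals.

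An estimated correlation and fry gave 0 lists in each of the 3 comparisons, where 16, 6 and 8 passed with the preset correlation and with RLE. Leaving out each library gave 11 to 15 lists for SCNT against ICSI, 5 to 8 for TR against ICSI and 9 to 15 for TR against SCNT. With SCNT replicates 1 and 3 left out together, which leaves 1 SCNT library assumed to vary like the rest, 11 lists passed for SCNT against ICSI and 15 for TR against SCNT. With the decidual covariate 7 lists passed for SCNT against ICSI. The share of genes with TR nearer ICSI was 41.66% of the higher and 64.06% of the lower genes, and ran from 41.84% to 66.25% as each library was left out.

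With SCNT replicates 1 and 3 left out together, the mean log2 fold change for SCNT against ICSI turned to 0.0737 for the cytotrophoblast list, -0.80 for the macrophage list, -1.15 for the inflammatory list, -0.0933 for the decidual list, -0.90 for the endometrial epithelium list and -0.026 for the ribosomal list, and for TR against SCNT to -0.19 for the cytotrophoblast list and 0.0489 for the matrix list. The log2 fold changes of genes also turned, to -0.0277 for VSIG4, -0.46 for FOLR2, -0.46 for SNRPN, -2.97 for IGFBP1, -3.58 for KLK3 and -0.13 for TIMP3 for SCNT against ICSI, and to 6.44 for IGFBP1 for TR against SCNT. With the decidual covariate, the lists that turned for SCNT against ICSI were cytotrophoblast (0.12), macrophage (-0.78), decidual (-0.20), endometrial epithelium (-0.37), inflammatory (-0.64) and ribosomal (-0.051), and for TR against ICSI decidual (-0.47) and ribosomal (-0.0473). Genes that turned with it were MARCO (-0.0835), VSIG4 (-0.20), FOLR2 (-0.48), SNRPN (-0.58), IGFBP1 (-2.36), KLK3 (-3.20) and TIMP3 (-0.30) for SCNT against ICSI, HAND2 (-0.14) and IGFBP1 (-0.52) for TR against ICSI, and IGFBP1 (1.84) for TR against SCNT. With limma-voom IGFBP1 turned to 1.09 for TR against SCNT. The covariate was the level of the decidual list itself, so the fall of that list with it was fixed by the setting, and its members IGFBP1 and HAND2 entered the covariate. The cause was not tested for the other turns.

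At the spread of these libraries edgeR recovered 1 of 67 simulated genes with a 4-fold change, so a single-gene change of that size was seldom detectable with that test. The other tools were not simulated.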

Other observations

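The tests in this part were chosen after the result was seen, apart from the main values they are set against and the test with an estimated correlation. Embryonic globins had their highest levels in SCNT replicates 2 and 3. HBZ, the embryonic alpha-like globin, measured 0.32, 17.9 and 4.80 CPM in SCNT replicates 1, 2 and 3, 0.15 and 0.06 in ICSI and 1.34 in TR. HBE1, the embryonic beta-like globin, measured 0.05, 14.1 and 5.20 CPM in SCNT, 0.07 and 0 in ICSI and 0.77 in TR. Both globins were chosen after their values were seen. IFI27, an interferon-induced mitochondrial protein, measured 434 CPM in TR, 390 and 169 in SCNT replicates 3 and 1, 6.58 in SCNT replicate 2, and 47.7 and 18.7 in ICSI. Lymphoid markers were lowest in SCNT replicate 2, at a mean log2 CPM of 0.74 against 2.72 to 4.05 in the other 5 libraries.

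The syncytiotrophoblast and cytotrophoblast lists were lower, and the decidual and macrophage lists higher, in SCNT as a group. A differing share of maternal decidua in the pieces sequenced may explain this: in SCNT replicate 2, the SCNT library with the lowest decidual level, the syncytiotrophoblast list lay -0.28 from the ICSI mean, less than the ICSI SD of 0.35. Without the erythroid genes and the 20 genes with most counts the mean log2 fold change of the syncytiotrophoblast list was -1.02 against -1.07 with them. TMM scaling already trims genes of extreme fold change, so leaving these genes out could change little. Whether a few genes taking most of the counts played a part is not decided by this setting. A change in the share of trophoblast made by cloning itself stays open, as do placental region and stage, which the sources used do not give.

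The 10 named genes, PAPPA and FABP3 among them, were low in every SCNT library. With the decidual level as a covariate their median log2 fold change was -5.02 (median SE 0.56) against -5.23 without it, while edgeR's adjusted p was 0.955 to 1 with it and none of the 10 passed without it. The genes were picked for small p and for the side of each SCNT library, so the sign was fixed and the size is likely too large. Genes alike in all 3 SCNT libraries, whose decidual levels differ, were also bound to change little with the covariate. The covariate therefore cannot decide the part of decidua for these 10. Genes were therefore also chosen without SCNT replicate 2, the library with an ICSI-like decidual level, and then read in it. Of the 10 of smallest p chosen in this way, a partly different set, 10 lay below both ICSI libraries in replicate 2 (median log2 difference -1.96), as did 73 of the first 100 (median -0.72) and 33.8% of all genes. The ICSI libraries served both the choice and the reading, so chance stays open for each gene. The choice favours genes high in both ICSI libraries, which by itself tends to place another library below them. The share over all genes is not matched for this choice. The replicate 2 values therefore do not decide whether the share of decidua was the whole cause. They show that the low level of the 10 of smallest p was not confined to the libraries with a high decidual level. Of all 4376 genes lower in replicates 1 and 3, 41.7% lay below both ICSI libraries in replicate 2 (median -0.06), so most of these genes did not share the low level there. A shared donor genome or donor cell type of the clones, stage, region, sex, what the alignment codes mark and an effect of nuclear transfer stay open and were not tested.

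The erythroid list was higher in all 3 SCNT libraries. With the decidual level as a covariate its mean log2 fold change was 2.84 against 2.51 without it (camera adjusted p = 1.02e-06). Without the covariate, the estimated correlation gave this list an adjusted p of 0.733. The list was alike in all 3 SCNT libraries, whose decidual levels differ, so its fold change was bound to change little with the covariate. The covariate also follows decidual stroma and does not measure blood. It therefore cannot decide the part of decidua and its blood. SCNT replicate 2, with a decidual level of 3.25 against 3.86 and 1.17 in ICSI, had an erythroid level of 3.65 against 0.945 and 1.82. The difference was thus not confined to the libraries with a high decidual level. The difference was spread over the list, since 9 of 15 members had every SCNT library above both ICSI libraries, where chance gives 1.5. More fetal or maternal blood in the pieces, an earlier stage of development, and more red cell formation in cloned placentas may each explain it and were not tested.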
